A study of Homo sapiens with 8 samples.

How the data were processed

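Total RNA from 8 samples of FULVR cells, 4 given 2 µM verteporfin for 24 h and 4 given vehicle, was sequenced from libraries made with a kit for Illumina sequencing, per the labels' protocols. The labels gave each sample its treatment and replicate number. TopHat, SAMtools, HTSeq, DESeq2 and the build hg19 are named in the submitters' processing notes, without versions; the annotation and the strand setting were not given in the sources used here. The authors deposited 1 table of normalized counts per gene, a signal in which each library's read counts were divided by 1 size factor. In each library every value above 0 was a whole multiple of the smallest value, within 0.001 of a read for 100% of values, which gives back whole reads. For vehicle replicate 4 and verteporfin replicate 1 the size factors were close to 1 (1.01 for both), and an independent check of the deposited values did not accept recovered reads there, so the count tests took 6 libraries, 3 per group. Recovered reads ran from 43578094 to 58889368 per library in those 6.

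From the deposited normalized counts the following was computed in R 4.3.3. The main test was limma 3.58.1 (lmFit and eBayes with an intensity trend, two-sided) on log2(value + 1), for genes with a mean normalized count of at least 10 over all 8 libraries, with group as the only term and Benjamini-Hochberg adjustment at 0.05. Since the values are not raw counts, no count test was the main one. As alternatives, edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 were run on the recovered reads of the 6 libraries. Gene lists, fixed before the data were examined, were tested with camera (limma, preset correlation 0.01) where at least 5 members were tested, with fry and camera with an estimated correlation beside it. Of 28 lists, 27 could be tested. Names in the table were matched to current or older symbols. In 27 names a spreadsheet had turned the gene symbol into a date; 23 of these passed the filter, stayed in the tests and are not named.

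Named genes followed a rule set before the data were examined. It took the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 50 and separated groups, leaving out clone-based, LOC, LINC, MIR, SNOR and pseudogene-like names; 17 fixed genes of the Hippo, estrogen and porphyrin response; and per list the 2 passing members with the largest rise and the 2 with the largest fall, or every passing member where a list had 5 or fewer. Genes named outside the rule are marked as chosen after their values were seen; these include the ribosomal RNA genes RNR1 and RNR2 and the nuclear RNAs NEAT1 and MALAT1.

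Protein classes were made from GENCODE release 29 coding transcripts (Python 3.11.15, numpy 2.4.6, pandas 2.3.3), 1 transcript per gene, joined by symbol, so that no coordinates were used. A protein was called ER-targeted if a window of 10 residues within the first 35 had a mean Kyte-Doolittle hydropathy above 2. It was also called so if it had at least 3 separate windows of 19 residues with a mean of at least 1.6. Proteins without such an N-terminus and without any such segment formed the comparison class. The rest formed an unclear class, which was kept in the matching. List members outside the ER-targeted class include unclear ones. The rule marked 14 of 16 ER chaperone genes and 7 of 10 ERBB receptor and ligand genes. It marked 0 of 24 ribosomal protein genes and 0 of 23 genes of G1/S and DNA replication. Per-library scores were medians over genes of the log2 value minus the gene's vehicle mean, compared by two-sided exact permutation of the 8 libraries.

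On simulated data with the real means and library sizes, limma over 15160 genes recovered 40% of 50 genes changed 1.25-fold, 90% at 1.5-fold, 100% at 2-fold and 100% at 4-fold, with 5.70% of its calls false. On 6 simulated libraries edgeR recovered 18%, 88%, 96% and 100% with 2.92% of calls false, and DESeq2 50%, 90%, 96% and 100% with 15.6% false. The simulation changed far fewer genes than were called in the real data, all with a mean of at least 50. The adjusted p threshold was therefore stricter there, and these rates do not carry over directly to the real comparison. Replicates were compared before use, and no pair of libraries agreed within sampling noise (chi-square per gene from 7.50 to 112), so none was counted as a duplicate. Alternatives covered the pseudocount, the filter, the scaling, the variance model, the replicate number as a block and leaving out each library. Those added after the data were seen were limma on the 6 libraries, leaving out verteporfin replicates 1 and 2 together, the antisense score as a covariate, and the limits of the protein classes.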

Results

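The data were RNA-seq profiles of FULVR cells, a human breast cancer cell line derived from MCF7 that is resistant to fulvestrant, a drug that degrades the estrogen receptor. The cells had received 2 µM verteporfin for 24 h in 4 samples and vehicle for 24 h in 4 samples. Verteporfin is a porphyrin-type photosensitizer that is also known to interfere with the binding of YAP to the TEAD transcription factors. The title of the series concerns VGLL1, a cofactor of TEAD proteins, and the design implied 1 comparison, which asked what transcripts differed after verteporfin. The deposited table listed normalized read counts for 27915 genes, and 6726 of them were at 0 in every library. Totals of the normalized counts ran from 46820991 in verteporfin replicate 3 to 55066167 in vehicle replicate 1. In the 6 libraries used for count tests, recovered reads ran from 43578094 in verteporfin replicate 2 to 58889368 in vehicle replicate 1. Fold changes were measured on the log2(value + 1) scale, which understates the change of genes with low counts, over 15160 genes with a mean normalized count of at least 10. The labels did not state that replicates came from separate cultures, so the p-values measured only the spread between these samples, which may be technical.

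Verteporfin lowered many transcripts several-fold and raised few by as much. TNC, which encodes the matrix glycoprotein tenascin C, fell from 255 ± 10.1 to 8.40 ± 3.44 normalized counts (mean ± SD, n = 4 each), a log2 change of -4.84 (SE 0.25; limma adjusted p = 2.97e-08). DAG1 (dystroglycan) fell by 4.77 on the log2 scale, LTBP1 (a TGF-beta binding matrix protein) by 4.55 and APP (the amyloid precursor protein) by 4.46, the last from 50506 ± 2217 to 2332 ± 557 normalized counts. The other 6 of the 10 largest falls were CLSTN2, FN1 (fibronectin), FBN1 (fibrillin), GPC3, PCDHGB5 and EDIL3, with log2 changes between -4.26 and -4.20. The 10 largest rises, in a ranking that left out MIR, SNOR and clone-based names, were smaller and included RPPH1, the RNA of RNase P, which rose 3.48-fold (SE of the log2 change 0.25; limma adjusted p = 1.34e-04), TERC, the telomerase RNA, and SCARNA2, a small Cajal body RNA, which rose by 1.30 and 1.17 on the log2 scale. Among protein-coding genes, MSS51 rose by 1.16, C6orf141 by 1.02, CDRT1 by 0.99 and ME3, a mitochondrial malic enzyme, by 0.95 on the log2 scale.

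Of the 15160 genes tested, 7641 changed (50.4%), with 3368 higher and 4273 lower after verteporfin (limma, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes numbered 1922, of which 106 were rises and 1816 were falls. The number of such rises was less stable. It was 252 without verteporfin replicate 2, 71 without verteporfin replicate 1, 292 with upper-quartile scaling and 28 with a pseudocount of 8. All 4 verteporfin libraries lay on one side of all 4 vehicle libraries for 7134 genes, 47.1% of those tested, where chance gives 2.86%. The first principal component held 75.6% of the variance and separated the groups, and the second held 11.6% and placed verteporfin replicates 1 and 2 at its ends. The split between rises and falls depended on the scaling. With upper-quartile scaling the median log2 change of the tested genes moved up by 0.19, with quantile scaling by 0.17 and with scaling to equal totals by 0.16, and 68.0%, 67.2% and 65.1% of the calls were then rises, against 44.1% with the deposited scaling. The directions given below were those under the deposited scaling. STAM-AS1 (1.20) and MELTF-AS1 (1.02), both among the 10 largest rises, are antisense genes. The sources used here did not state that counting used strand, so reads of such genes and of their sense partners could not be told apart. PCDHGB5 shares exons with other members of its protocadherin cluster and its value is uncertain for that reason.

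Transcripts of the YAP-TEAD target list mostly fell, and EGFR fell with them. CTGF and CYR61 (now CCN2 and CCN1), secreted matricellular proteins commonly used as readouts of YAP-TEAD activity, fell 3.77-fold and 3.41-fold, with log2 changes of -1.91 (SE 0.11) and -1.77 (SE 0.10; limma adjusted p = 6.73e-08 and 4.64e-08). Levels of CTGF went from 982 ± 49.9 to 262 ± 39.0 normalized counts (mean ± SD, n = 4 each). CRIM1 and CCDC80, a membrane and a matrix protein, fell 7.50-fold and 6.98-fold. The target genes ANKRD1 and GADD45A went the other way and rose by 0.58 and 0.44. EGFR, the epidermal growth factor receptor, fell 7.82-fold, from 6799 ± 534 to 877 ± 164 normalized counts (log2 change -2.97, SE 0.12; limma adjusted p = 4.41e-09).

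**Figure D1:**
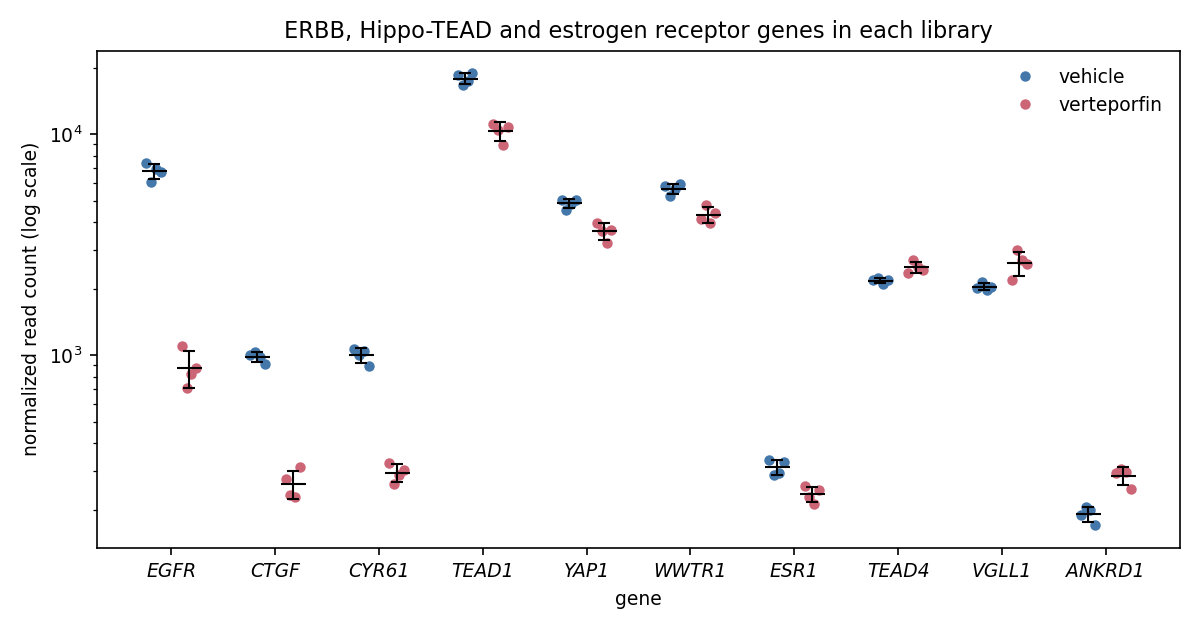
Normalized read counts (log scale) of 10 genes in each of the 4 vehicle and 4 verteporfin libraries; points are libraries and bars are the mean ± SD. EGFR lies near 6799 in vehicle and 877 in verteporfin, while VGLL1 and ANKRD1 lie higher in verteporfin.

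Of the 20 tested YAP-TEAD targets, 14 fell, 2 rose and 4 did not pass, and adjusted over the list alone 16 fell and 2 rose. The set test gave an adjusted p of 2.99e-04 (limma camera) for a list lower than other genes, and adjusted p = 0.655 with an estimated correlation. AXL, a further member, lay below the expression filter at 7.26 ± 2.49 and 3.57 ± 1.29 normalized counts. The 8 targets predicted to be made at the endoplasmic reticulum, a class described below, had a median log2 change of -2.04 and all 8 fell. Among the other 12 targets the median was -0.25, with 6 lower and 2 higher. Among genes of the same class and length quintile, CTGF lay at the 14.1 percentile, CYR61 at 18.4, CRIM1 at 10.8, CCDC80 at 13.4 and EGFR at 10.2, all within the range of similar genes. The ERBB receptor and ligand list had 7 falls, 0 rises and 3 members that did not pass among 10 tested, with the same numbers adjusted over the list alone. ERBB3, a partner receptor of ERBB2, fell by 2.31 on the log2 scale. The set test gave an adjusted p of 0.00636 (limma camera), and adjusted p = 0.655 with an estimated correlation, and 7 of the 10 members belonged to the same predicted class. Its median lay at the 18.6 percentile of lists matched on class and length, within their range.

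Within the Hippo pathway, TEAD1 fell and was the only 1 of the 4 TEAD genes to do so, and VGLL1 rose. TEAD1 had a log2 change of -0.79 (SE 0.08), YAP1 of -0.43 (SE 0.07) and its paralog WWTR1, which encodes TAZ, of -0.39 (SE 0.07), with limma adjusted p = 8.80e-06, 6.82e-04 and 0.00118. VGLL3 fell by 1.08 and the kinase gene TAOK1 by 1.00 on the log2 scale. VGLL1 rose by 0.35 (SE 0.09; limma adjusted p = 0.00741), from 2039 ± 71.6 to 2614 ± 329 normalized counts. Among genes of the same class and length quintile VGLL1 lay at the 62.0 percentile and TEAD1 at 0.966. YAP1 lay at 7.56, WWTR1 at 9.42 and TAOK1 at 3.03, all above the 2.5 percentile, and VGLL3 lay at 2.11, below it. TEAD4 rose by 0.20 (SE 0.06; limma adjusted p = 0.0226), and the call was lost without vehicle replicate 1, 3 or 4 (limma adjusted p = 0.0553, 0.0700 and 0.0559) and with the replicate number as a block (0.0562). TEAD2 and TEAD3 had log2 changes of 0.08 and 0.09 (SE 0.06 and 0.08) and did not pass; both passed as higher with upper-quartile (0.28 and 0.29), total (0.25 and 0.25) and quantile (0.28 and 0.29) scaling. Of the 24 members of the Hippo-TEAD list, 16 fell, 3 rose and 5 did not pass, and adjusted over the list alone 17 fell and 3 rose. The set test gave an adjusted p of 0.00927 (limma camera) for a lower list, and adjusted p = 0.671 with an estimated correlation. Of its 22 members with a protein class, 0 were predicted to be made at the endoplasmic reticulum, and the list median lay at the 0.02 percentile of lists matched on class and length.

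Transcripts of proteins predicted to be made at the endoplasmic reticulum fell more often and by more than others. This grouping was chosen after the values were seen. Each tested gene that matched a coding transcript, 13043 of 15160 (86.0%), was classed from its protein sequence by a hydrophobic N-terminus or by at least 3 hydrophobic segments, features of proteins made at the endoplasmic reticulum (ER). Among 3097 predicted ER-targeted genes, 2073 fell (66.9%) and 175 rose, with a median log2 change of -0.95. Among 8180 genes with neither feature, 1450 fell (17.7%) and 2408 rose, with a median of 0.12. The remaining 1766 matched genes were unclear, and of these 585 fell (33.1%) and 334 rose, with a median of -0.03. Predicted ER-targeted genes were 23.7% of the matched genes and 83.6% of the matched genes that fell at least 2-fold. Per library, the median of the ER-targeted class minus that of genes with neither feature differed between the groups by -1.07 on the log2 scale. The SE was 0.09 (n = 4 each, two-sided exact permutation p = 0.0286, the smallest this design allows). With a looser limit for the N-terminus the difference was -0.68. With the main limit it was -0.53 in the shortest quintile of transcripts and -1.26 in the longest. Genes of the ER-targeted class and genes with neither feature had lower medians among longer transcripts.

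**Figure D2:**
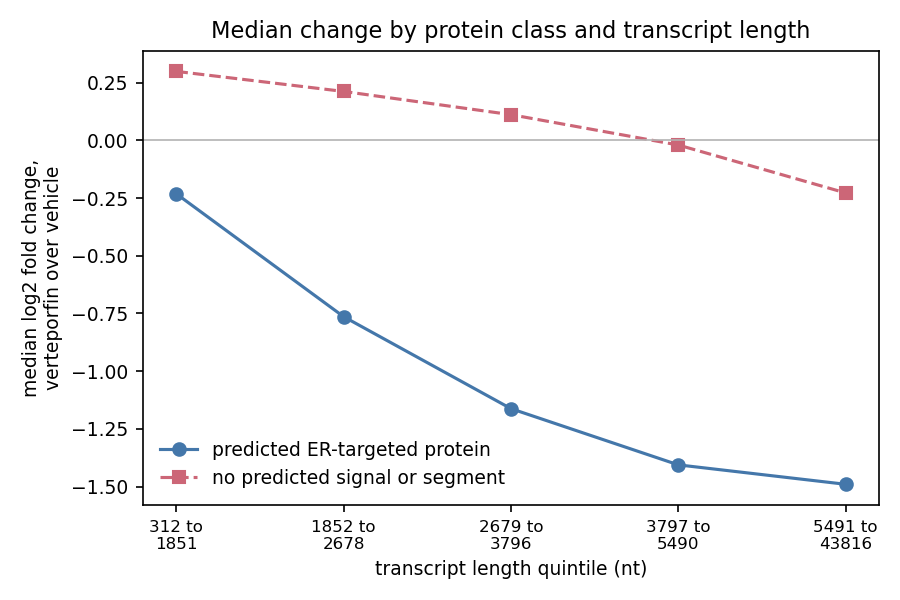
Median log2 fold change, verteporfin over vehicle, by quintile of transcript length (nt) for genes predicted to encode ER-targeted proteins (circles) and for genes with no predicted signal or segment (squares). The first class goes from -0.23 to -1.49 and the second from 0.30 to -0.23.

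Other measures of library content moved with the treatment too. RNR1 and RNR2, taken here as the mitochondrial ribosomal RNA genes, rose by 0.83 and 0.47 on the log2 scale (SE 0.11 and 0.13, limma adjusted p = 7.49e-05 and 0.0135). The annotation was not given, so their identity rests on the symbols alone. Together they took 0.589% to 0.823% of the counts in vehicle libraries and 1.12% to 1.26% in verteporfin libraries. The median log2 level of 428 antisense genes was higher by 0.24 in verteporfin (SE 0.09, n = 4 each; two-sided exact permutation p = 0.0286). These sets, and the 5 genes named here, were chosen after the values were seen. Verteporfin replicate 1 lay at 0.50 on this measure and replicate 2 at 0.11, relative to the vehicle mean of each gene. MIR6087, an entry with the name of a microRNA gene that the ranking above left out, rose 12.1-fold. It went from 1677 ± 354 to 20257 ± 4752 normalized counts (mean ± SD, n = 4 each). The log2 change was 3.59 (SE 0.17, limma adjusted p = 1.37e-08). Counts per gene do not tell which RNA these reads came from, so a rise of the microRNA itself was not shown. The nuclear RNAs NEAT1 and MALAT1 had log2 changes of 0.48 (SE 0.30) and 0.42 (SE 0.22) and did not pass.

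Most ER chaperone genes and most of the tested estrogen receptor targets fell. HSPA5, the main chaperone of the endoplasmic reticulum, fell from 39482 ± 1959 to 3919 ± 1197 normalized counts (mean ± SD, n = 4 each; log2 change -3.38, SE 0.17), and SEL1L, a component of ER-associated degradation, fell by 3.50 on the log2 scale (SE 0.11). Of the 16 ER chaperone genes, 14 fell, 0 rose and 2 did not pass, and adjusted over the list alone 15 fell and 1 rose. This list had the smallest adjusted p of the 27 lists tested, 1.57e-06 (limma camera), and adjusted p = 0.655 with an estimated correlation. Its 14 members of the predicted ER-targeted class had a median log2 change of -2.31, and the list median of -2.01 lay at the 0.03 percentile of lists matched on class and length. ESR1, the estrogen receptor, went from 311 ± 24.6 to 235 ± 18.8 normalized counts (log2 change -0.40, SE 0.11; limma adjusted p = 0.00921), a call that was lost under upper-quartile (-0.21), total (-0.24) and quantile (-0.18) scaling. Its targets CA12, a carbonic anhydrase, and CTSD, cathepsin D, had log2 changes of -2.81 and -2.73, whereas KRT13 and FKBP4 rose by 1.03 and 0.31. GREB1 had a log2 change of -0.07 (SE 0.18) and did not pass, and PGR, the progesterone receptor, lay below the filter at 0.277 ± 0.554 and 0.694 ± 0.907 normalized counts.

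In the estrogen receptor target list, 19 of 24 members were tested, and PGR, TFF1, TFF3, PDZK1 and SGK3 lay below the expression filter. Of the 19 tested genes 14 fell, 2 rose and 3 did not pass, with the same numbers adjusted over the list alone. The set test gave an adjusted p of 0.00122 (limma camera), and adjusted p = 0.529 with an estimated correlation. Its 9 members of the predicted ER-targeted class all fell, with a median log2 change of -2.04, and the other 10 had a median of -0.16. Of 19 luminal epithelial genes 13 fell, 3 rose and 3 did not pass, and adjusted over the list alone 14 fell and 3 rose (limma camera adjusted p = 0.00344; adjusted p = 0.668 with an estimated correlation). CDH1 (E-cadherin) and OCLN (occludin) fell by 3.86 and 2.56 on the log2 scale, and the keratin gene KRT19 rose by 0.44. Of 14 basal and mesenchymal genes 8 fell, 2 rose and 4 did not pass, with the same numbers adjusted over the list alone (limma camera adjusted p = 0.0222; adjusted p = 0.655 with an estimated correlation). FN1 and CDH2 (N-cadherin) fell by 4.26 and 3.26, and the keratin genes KRT16 and KRT17 rose by 0.81 and 0.71. The call for this last list was lost without a filter (0.139), with a mean of at least 50 (0.120) and without verteporfin replicates 1 and 2 (0.0535, camera adjusted p).

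Most tested genes of the proliferation lists, 18 of 23 and 15 of 20, rose by small amounts. In the G1/S and DNA replication list 18 of 23 genes rose, 0 fell and 5 did not pass, and adjusted over the list alone 19 rose and 0 fell (limma camera adjusted p = 2.35e-04; adjusted p = 0.668 with an estimated correlation). RFC4, a clamp loader subunit, rose by 0.67 (SE 0.07) and CDC45, part of the replicative helicase, by 0.55 (SE 0.07) on the log2 scale. In the G2/M list 15 of 20 rose, 1 fell and 4 did not pass, and adjusted over the list alone 16 rose and 1 fell (limma camera adjusted p = 2.99e-04; adjusted p = 0.671 with an estimated correlation). The mitotic kinase genes AURKB and CDK1 rose by 0.63 and 0.57, and MKI67 fell by 0.67. Of the members of these lists, 0 of 23 and 0 of 20 were predicted to be ER-targeted.

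**Figure D3:**
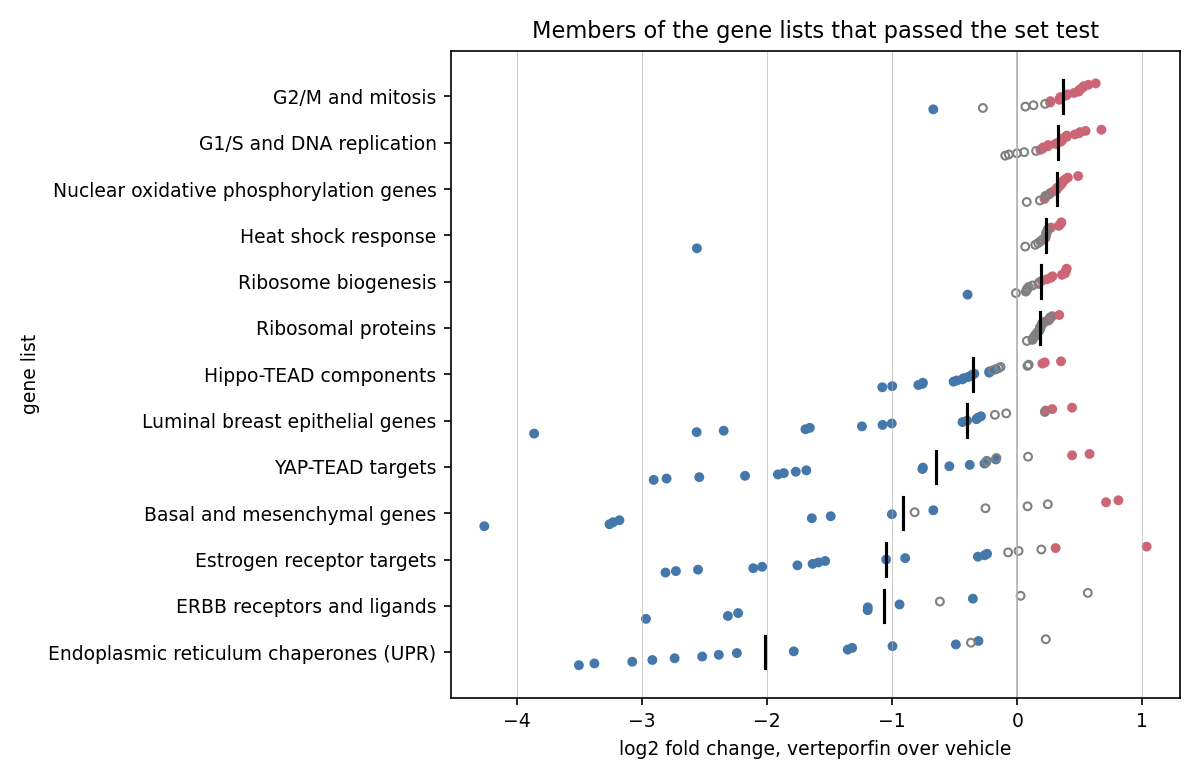
Log2 fold change, verteporfin over vehicle, of each tested member of the 13 gene lists that passed the set test with the preset correlation. Filled points passed the gene test (blue lower, red higher), open points did not, and black lines are list medians, from -2.01 for the endoplasmic reticulum chaperones to 0.37 for G2/M genes.

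Most nuclear oxidative phosphorylation genes rose by small amounts, as did 9 of 18 ribosome biogenesis genes, while most ribosomal protein and heat shock genes did not pass. Against lists matched on class and transcript length, the medians of the oxidative phosphorylation, heat shock and ribosome biogenesis lists lay at the 95.2, 84.2 and 80.2 percentiles, within the range of those lists. Of 18 nuclear oxidative phosphorylation genes 14 rose, 0 fell and 4 did not pass, and adjusted over the list alone 15 rose and 0 fell (limma camera adjusted p = 8.98e-04; adjusted p = 0.671 with an estimated correlation). NDUFV1, a complex I subunit, rose by 0.49 and UQCRC2, of complex III, by 0.40 on the log2 scale. Of 18 ribosome biogenesis genes 9 rose, 1 fell and 8 did not pass, with the same numbers adjusted over the list alone (limma camera adjusted p = 0.00636; adjusted p = 0.671 with an estimated correlation). GNL3 and NOP58, nucleolar proteins, rose by 0.40 and 0.39, and POLR1A, the largest subunit of RNA polymerase I, fell by 0.40. Of 24 ribosomal protein genes 3 rose, 0 fell and 21 did not pass, and adjusted over the list alone 0 rose and 0 fell (limma camera adjusted p = 0.00755; adjusted p = 0.817 with an estimated correlation). RPL27 rose by 0.34 on the log2 scale. In the heat shock list 6 of 16 rose, 1 fell and 9 did not pass, with the same numbers adjusted over the list alone (limma camera adjusted p = 0.0167; adjusted p = 0.817 with an estimated correlation). CHORDC1 rose by 0.35 and HSPA1A, whose near-identical copy HSPA1B makes its value uncertain, by 0.35, and the member that fell was SERPINH1, a collagen chaperone of the endoplasmic reticulum, by 2.56.

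Several lists moved in both directions and did not pass the set test. Of 23 cholesterol genes 10 rose, 12 fell and 1 did not pass, and adjusted over the list alone 11 rose and 12 fell (limma camera adjusted p = 0.469). HMGCR, the rate-limiting enzyme of cholesterol synthesis, fell by 2.30 and DHCR24 by 2.77 on the log2 scale, while FDPS and MVD, soluble enzymes of the same pathway, rose by 0.57 and 0.56. Of 20 integrated stress response genes 8 rose, 4 fell and 8 did not pass, and adjusted over the list alone 8 rose and 5 fell. ASNS and ATF3 both rose by 0.58, and the amino acid transporter genes SLC7A5 and SLC7A11 fell, with log2 changes of -3.34 and -2.94. The camera direction of this list was up (adjusted p = 0.526) and its median was 0.11, while its mean was -0.21. Of its 3 predicted ER-targeted members 2 fell and 0 rose (median -2.94), and of the other 17, 2 fell and 8 rose (median 0.19). Of 22 lysosome and autophagy genes 4 rose, 11 fell and 7 did not pass, and adjusted over the list alone 5 rose and 11 fell. GNS and LAMP1, a lysosomal hydrolase and membrane protein, fell, with log2 changes of -3.84 and -2.84, and SQSTM1 and TFEB rose by 0.39 and 0.56. All 10 predicted ER-targeted members of this list fell (median -2.23), and of the other 12, 1 fell and 4 rose (median 0.17). The set test gave an adjusted p of 0.0562 (limma camera) and passed without vehicle replicate 1, 3 or 4 (0.0470, 0.0452 and 0.0499) and without verteporfin replicate 3 or 4 (0.0388 and 0.0290), and also with a pseudocount of 8 (0.0499), without a filter (0.0140), and with upper-quartile (0.0323) and quantile (0.0330) scaling.

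Genes of heme metabolism and xenobiotic response, which bear on a porphyrin compound, changed in both directions. ALAS1, the first enzyme of heme synthesis, rose by 0.53 and PPOX by 0.54 on the log2 scale, while the transferrin receptor gene TFRC fell by 2.77 and the porphyrin exporter gene ABCG2 by 1.11. Of 21 heme and iron genes 8 rose, 6 fell and 7 did not pass (limma camera adjusted p = 0.589, median 0.15 and mean -0.13). Adjusted over the list alone the numbers were the same. The 4 predicted ER-targeted members all fell (median -0.81), and of the other 17, 2 fell and 8 rose (median 0.22). HMOX1, heme oxygenase, had a log2 change of 0.22 (SE 0.12; limma adjusted p = 0.139) and passed without verteporfin replicate 1 (0.30; limma adjusted p = 0.0304), with upper-quartile (0.42), total (0.38) and quantile (0.42) scaling, and with the antisense score as a covariate (0.51). CYP1A1, the classic target of the aryl hydrocarbon receptor (AHR), had a log2 change of -0.11 (SE 0.09; limma adjusted p = 0.331) and passed as lower with that covariate (-0.30; limma adjusted p = 0.0250). Among 10 AHR targets 4 rose, 3 fell and 3 did not pass, with ALDH3A1 and CYP1A2 higher by 0.87 and 0.70 and LRAT and CYP1B1 lower by 1.61 and 1.31 (limma camera adjusted p = 0.928 with direction up; median -0.02 and mean -0.18), and the numbers adjusted over the list alone were the same. Of 18 NRF2 targets 7 rose, 1 fell and 10 did not pass, OSGIN1 rising by 0.66 (limma camera adjusted p = 0.201), with the same numbers adjusted over the list alone.

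The remaining lists did not pass the set test, and in each the counts of rises and falls were the same when adjusted over the list alone. MAPK output genes had 0 rises, 6 falls and 10 that did not pass among 16 (limma camera adjusted p = 0.281). EPHA4 and EPHA2, both predicted ER-targeted, were lower by 2.38 and 1.63 on the log2 scale. They lay at the 24.7 and 42.2 percentiles of genes of their class and length quintile. Of 22 p53 targets 5 rose, 8 fell and 9 did not pass (0.684), with TP53I3 higher by 0.50 and GDF15 lower by 1.03. Hypoxia and glycolysis genes had 3 rises, 4 falls and 10 that did not pass among 17 (0.820), with ENO1 higher by 0.36 and P4HA1 lower by 2.46. Of 18 interferon-stimulated genes 4 rose, 4 fell and 10 did not pass (0.589), with IRF9 higher by 0.48 and RSAD2 lower by 0.71. NF-kB targets had 2 rises, 1 fall and 8 that did not pass among 11 (0.783), the rises being NFKBIA (0.39) and NFKB2 (0.32) and the fall ICAM1 (-2.07). The camera direction of the hypoxia and NF-kB lists was up while their means were -0.22 and -0.12. Of 19 apoptosis regulators 3 rose, 5 fell and 11 did not pass (0.815), with PMAIP1 higher by 0.43 and TNFRSF10A lower by 1.55. Of 9 histone genes, which share reads with near-identical copies, 1 rose, 1 fell and 7 did not pass (0.574; direction up, median -0.01 and mean 0.15). Markers of fibroblasts, endothelium and immune cells had 1 rise, 2 falls and 3 that did not pass among 6 tested (0.616), the falls being CDH5 (-1.47) and COL3A1 (-1.18), and 10 of the 16 markers lay below the filter. Of the 13 mitochondrially encoded protein genes, 0 were found under their MT- names, and other names for them were not searched.

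Of the 27 lists tested, 13 passed the set test with its preset correlation of 0.01 (6 up, 7 down), 0 passed with an estimated correlation, and 19 passed fry (limma), which asks whether a set moves on balance and compares it with no other genes. Heat shock genes and ribosomal protein genes passed camera and not fry (adjusted p = 0.134 and 0.158). Of the 35 ways to split the 8 libraries into 4 and 4, 5 gave at least as many lists, the real grouping included, so chance could not be excluded for the number of lists. The other 4 splits each kept 3 libraries of a treatment together, and splits with 2 of each on both sides gave at most 10 lists. Changes in single genes were called by count models too. On the 6 libraries used for count tests, edgeR's quasi-likelihood test called 7908 genes (3596 higher, 4312 lower) and DESeq2 called 7582 (3437 higher, 4145 lower). Of the rises and falls named above, those of STAM-AS1 (0.26), CDRT1 (0.44), PPOX (0.26), NFKB2 (0.18), POLR1A (-0.23) and COL3A1 (-0.92) no longer passed with the antisense score as a covariate, and that of TFEB did not pass in DESeq2 (adjusted p = 0.0585).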

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

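Which values counted as unusual was set before the data were examined: within a group of 4 libraries, 1 library far from the other 3 by Dixon's test at 95%. Chance alone gives about 1 in 20 such cases, and 15 of 300 checks met the rule (5%), so the number is that of chance. In the vehicle group, values lay apart for FBN1 in replicate 2 (3586 normalized counts, against 4564 to 4698 in the others), KRT16 in replicate 1 (478.8, against 404 to 416) and ABCG2 in replicate 1 (7477, against 6959 to 7006). Vehicle replicate 3 lay apart for KRT19 (50220, against 53429 to 53916), PGK1 (21490, against 23361 to 23692) and PGR (1.108, against 0 in the others). Vehicle replicate 4 lay apart for EPHA2 (2594, against 2773 to 2798) and NOP58 (6267, against 6611 to 6640). In the verteporfin group, replicate 1 lay apart for TEAD3 (7083, against 5714 to 5912) and for the histone gene HIST1H4C (71.52, against 57.0 to 59.1), whose reads may come from near-identical copies; with the antisense score of each library as a covariate, TEAD3 had a log2 change of -0.0933. Single values also lay apart for CHORDC1 in replicate 2 (3690, against 3444 to 3470), TAOK1 in replicate 3 (4691, against 6214 to 6474) and FAS in replicate 4 (212.7, against 138 to 149). Of the means over gene lists on the log2 scale, that of the Hippo-TEAD list lay apart in verteporfin replicate 3 (11.93, against 12.1 in each of the others) and that of the NF-kB list in vehicle replicate 1 (9.097, against 8.92 to 8.94).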

How the results depend on the processing

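The alternatives chosen after the results were seen were limma on the 6 libraries used for count tests, leaving out verteporfin replicates 1 and 2, the antisense score as a covariate and the limits of the protein classes. Of 114 named genes past the threshold, 95 kept their direction and their side of it in all 24 settings, and 0 genes called in both the main test and an alternative had opposite directions. Over the tests without 1 library, 6270 to 8579 genes changed, 2442 to 3977 higher and 3805 to 4602 lower, 1850 to 2030 changed at least 2-fold, and 13 to 14 lists passed. The count of higher genes rose to 6810 with upper-quartile, 6278 with total and 6686 with quantile scaling, which move the median gene. Filters of a mean of at least 50 and of none gave 7324 and 7338 changed genes, limma without an intensity trend 7207, limma on 6 libraries 7637, the antisense covariate 8090 and the test without verteporfin replicates 1 and 2 8577. With the replicate number as a block (replicate block), 6474 genes changed, of which 6461 were shared, and 13 lists passed; 0 of the 4 vehicle libraries correlated best with the verteporfin library of the same number (correlations -0.33, -0.16, 0.07 and 0.04). Camera with an estimated correlation passed 0 lists; 10 of the 13 passing lists were the same in all other settings. Among genes that did not pass, the sign turned for TEAD3 (-0.0933, antisense covariate), GREB1 (0.119 upper-quartile, 0.0872 total) and CYP1A1 (0.0819 upper-quartile, 0.0497 total, 0.106 quantile); the cause was not tested. Lists that did not pass camera turned direction as follows (adjusted p): under fry, which sums over members, the integrated stress response (0.0474), heme (0.156), AHR (0.0120), hypoxia (0.0125) and NF-kB (0.845) lists; AHR without a filter (0.973), with upper-quartile scaling (0.990) and without vehicle replicate 4 (0.997) or verteporfin replicate 4 (0.889), in a range of 0.865 to 0.997 over the tests without 1 library; p53 with quantile scaling (0.933); and apoptosis regulators with upper-quartile (0.892), total (0.856) and quantile (0.933) scaling. The difference between protein classes moved to -0.68 with a looser N-terminal limit, was -1.22 with the antisense covariate and lay between -1.20 and -1.01 otherwise. In the simulation 40% of 1.25-fold changes were found. It held far fewer changed genes than the real comparison, so that share does not carry over. Genes that did not pass may still have changed by that much.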

Other observations

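The gene families, protein classes and cholesterol genes described in this part and the tests of length, hydrophobic segments and unspliced RNA were chosen after the values were seen; the comparison of the YAP-TEAD list and EGFR with matched genes, the test of U content and the splits of the libraries were written down before their results. Families were taken by the start of the gene symbol and membership was not checked, so other genes with the same stem may be counted. Most members of several such families of surface and matrix proteins fell. Of 57 protocadherin genes, adhesion proteins that share exons and therefore reads within their clusters, 44 fell and 1 rose (median log2 change -2.42), and of 9 frizzled receptors for WNT ligands, 9 fell (-2.19). Ephrin receptors had 12 falls among 13 genes (-1.67), laminins 7 among 10 (-1.52) and collagens 15 among 27 (-0.94), with no rises, and ADAM proteases had 17 falls and 1 rise among 33 (-0.88). SLC transporters other than the mitochondrial SLC25 carriers had 162 falls and 7 rises among 217 genes (-1.23). Rises in families of soluble or mitochondrial proteins were smaller. Of 80 genes with mitochondrial ribosomal protein symbols (MRPL, MRPS) 59 rose and 0 fell (median 0.34). Of 50 genes with the complex I stem NDUF 37 rose and 1 fell (0.33). Of 52 genes with the proteasome stem PSM 36 rose and 2 fell (0.32), and of 45 SLC25 carriers 12 rose and 4 fell (0.20). Each of these families had a two-sided exact permutation p of 0.0286, the smallest this design allows (adjusted p = 0.0374 over 17 families). Host genes of small nucleolar RNAs had 18 rises and 1 fall among 21 (median 0.66; exact permutation p = 0.0286). Zinc finger genes had 75 rises and 79 falls among 452 (median 0.04, exact permutation p = 0.886). Vacuolar ATPase genes had 6 and 6 among 21 (0.02, exact permutation p = 0.514). Genes with the stem RAB had 6 and 18 among 62 (-0.07, exact permutation p = 0.143). The RAB median turned positive with upper-quartile (0.12), total (0.09) and quantile (0.12) scaling.

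Cholesterol genes split by the same protein classes. The 8 predicted ER-targeted genes of the list had a median log2 change of -1.98, with 7 falls and 1 rise, and the other 15 a median of 0.36, with 9 rises and 5 falls. LDLR, the receptor for LDL uptake, and SQLE, squalene epoxidase, fell, with log2 changes of -2.08 and -2.18, while HMGCS1, the soluble enzyme ahead of HMGCR in the pathway, rose by 0.31. Proliferation genes stood apart from other genes of their class and length: the median of the G1/S list lay at the 99.95 percentile and that of the G2/M list at the 99.96 percentile of 10000 lists matched on both, although neither call held with an estimated correlation (adjusted p = 0.668 and 0.671). Ribosomal protein genes had a median of 0.18 against 0.27 in lists matched in this way (3.62 percentile). Genes with the integrin stems ITGA or ITGB had 10 falls and 6 rises among 19 (median -1.61, quartiles -2.33 and 0.42). Whether the genes that rose encode integrins was not checked.

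The fall of mRNAs for predicted ER-targeted proteins was weighed against 3 technical explanations, transcript length, the share of unspliced RNA and coding sequence. Transcript length does not account for it, since the difference between classes within length quintiles was -1.07 on the log2 scale (SE 0.08). With the antisense score as a covariate the difference was -1.22 (SE 0.11). Whether that score measures the share of unspliced RNA was not tested, and it differs between the groups, so this explanation was not excluded. U-rich coding sequence does not account for the fall, since the difference within quintiles of U content was -1.04 (SE 0.09). SLC25 mitochondrial carriers, made on cytosolic ribosomes, lay 1.25 above other SLC genes with the same number of hydrophobic segments (27 and 11 genes). The SE of 0.19 was over libraries, not genes. With 1, 2 and 3 segments, 16 carriers met 2 other genes, 10 met 4 and 1 met 5. For these few genes the values argue against hydrophobic segments alone. What remains open may be biological, such as decay of mRNAs bound to the endoplasmic reticulum, or technical, such as a lower yield of membrane-bound RNA at extraction from cells holding a hydrophobic photosensitizer; these were not told apart by any value here. Measuring the same RNAs after another extraction, or a spike-in added before lysis, would be a test.

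The fall of YAP-TEAD targets and EGFR was weighed against the protein classes, since verteporfin is known to interfere with YAP-TEAD binding. The list median of -0.65 lay at the 1.38 percentile of 10000 lists matched on class and transcript length, below the 2.5 percentile set as the limit. Predicted class and length quintile alone seldom gave so low a median. The lists were not matched on expression level, and the class is a prediction that can miss members, so protein class was not excluded. Such matched lists ignore correlation between members, and the set test of this list gave adjusted p = 0.655 with an estimated correlation. EGFR lay at the 10.2 percentile of genes of its own class and length, CTGF at 14.1 and CYR61 at 18.4, so their falls are consistent with those of similar genes and need not reflect TEAD activity. Other lists lay lower among matched lists. Hippo-TEAD components, which share AMOTL2, LATS2 and PTPN14 with this list, lay at the 0.02 percentile. ER chaperones lay at 0.03, histone genes at 0.04 and estrogen receptor targets at 0.07. Basal and mesenchymal genes lay at 0.66, cholesterol genes at 1.03 and luminal epithelial genes at 1.13. The low position was therefore not specific to YAP-TEAD targets.

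Small non-coding RNAs were higher after verteporfin, by a median of 0.82 over 190 genes (SE 0.27, n = 4 each; exact permutation p = 0.0286), and for the 174 small nucleolar RNAs among them the exact permutation p was 0.0571 (adjusted p = 0.0694 over 17 families). With the antisense score as a covariate the difference was 0.15 (SE 0.15), which a larger share of unspliced RNA in the verteporfin libraries could give if antisense genes measure that share. The data did not decide it, since without verteporfin replicate 2 the difference with the covariate was 0.33 (SE 0.15), more than 2 SE above 0, and without replicate 1 it was -0.10 (SE 0.12). RPPH1 and TERC, the largest rises of small RNAs among the genes named by the rule, stayed higher with the covariate (2.21 and 1.28, limma adjusted p = 4.70e-05 and 0.00296). The antisense score therefore did not account for them. The covariate itself differs between the groups, and no biological explanation for these RNAs was tested.

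Splitting the 8 libraries into 4 and 4 in all 35 ways showed how often other groupings gave as much. For changed genes, higher genes, lower genes and genes changed at least 2-fold, 1 split, the real one, gave a count as large (7641, 3368, 4273 and 1922). The highest count in any other split was 0 each time. Those splits mixed both treatments within their groups, which adds the treatment difference to the spread. Their counts of 0 therefore do not tell how many calls chance gives. For gene lists, 5 splits gave at least 13, the real one included, and the highest other gave 14, so chance could not be excluded. All 4 others kept 3 libraries of a treatment together and so kept part of its difference; splits with 2 vehicle libraries on each side gave at most 10.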
